A study of Mus musculus with 8 samples.

How the data were processed

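RNA of 8 mouse kidney samples was measured, 4 labelled control and 4 labelled cinacalcet, with the group and replicate number taken from the sample titles. Total RNA was labelled with Cy3 and hybridised to one-colour Agilent arrays with 62976 spots each, per the labels and file headers. The deposited files are the scanner output of each array with spot intensity on a linear scale. Per the file headers they were made with Agilent Feature Extraction 11.0.1.1, while the submitters' processing notes name Agilent Feature Extraction 9.5. The processed intensity used here was background-corrected by that software, per the file headers, and no normalization between arrays is recorded there.

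Control spots were left out, leaving 59305 spots of 55681 probes per array. No spot was saturated, and 118 to 147 spots per array that the software marked as outliers were set to missing. Spots of a probe were averaged, and 31 probes with no usable spot on at least 1 array were dropped. The processed intensity was taken as log2 and the 75th percentile of each array was subtracted. The percentile itself ranged from 202.9 to 257.1 and the median intensity from 15.5 to 18.6. Probes well above background on at least 4 of 8 arrays were kept. The array number, 4 per group, limits the precision, and 51.8% to 58.0% of spots were well above background.

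The files hold accessions and no gene symbols, so probes were named through a RefSeq gene table of assembly GRCm38.p6 by accession without its version. This named 27235 probes with 1 gene each and left 28446 unnamed, and no probe had several names. No coordinates are given, because the array's own annotation was made on another build. Of the named probes 18601 passed the filter and gave 14209 genes, of which 3670 had more than 1 kept probe. The probe with the highest mean over the 8 arrays stood for its gene, and probes that disagreed are named in the results. Unnamed probes entered only a count over all kept probes.

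Groups were compared in limma 3.58.1 under R 4.3.3 with lmFit and eBayes, without covariates, and p-values were adjusted by the Benjamini-Hochberg method. Gene lists, 35 in all with 556 of 604 memberships measured, were fixed before the data were examined. Those with at least 5 measured genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The lists cover claudins, calcium, vitamin D, magnesium and phosphate handling, calcium-sensing receptor signalling, 9 kinds of kidney or immune cell, injury, metabolic, stress, hormone and clock pathways, and 5 other tissues. The counts of changed genes adjusted over a list alone use limma's p-values of its measured members.

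The genes named in the text follow a rule also fixed beforehand: 10 genes of mineral handling, the 12 largest rises and 12 largest falls among genes past an adjusted p of 0.05 whose groups do not overlap, and from each list up to 4 members past the threshold with the lowest p, or up to 2 where none passed. Genes named outside the rule are said to be. A gene not above background on any array of a group is given as a bound on its fold change.

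Alternatives planned beforehand were quantile normalization, normexp background correction with an offset of 50 followed by either scaling, other filters on dim probes, the median of detected probes as the scale, the mean over a gene's probes, eBayes with trend and robust settings, array weights, blocks for replicate number, slide row and slide column, fits within each slide row, and leaving out each array. Normexp was planned on the mean signal and used the median signal, which is the spot signal the files hold. A block for Y-linked signal and a fit to the 5 arrays with such signal were added after seeing the data. An array counts as lacking Y-linked signal where none of 4 measured Y-linked genes is well above background. All arrays were on 1 slide with 1 scan time, so slide and scan could not be tested as batches.

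The fit was tested on simulated data for the comparison of cinacalcet with control, with 14209 genes, the real means and spread, and 200 genes changed by known amounts. It recovered 36.0% of genes changed by 0.5 log2 units, 86.0% of those changed by 1, 98.0% of those changed by 2 and 100% of those changed by 3. It called 171 genes, 8 of them unchanged. A list of 54 genes lowered by 0.25 passed in camera and none of the other 33 lists did, in data without correlation between genes.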

Results

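Gene expression was measured in whole mouse kidney after 5 days of cinacalcet hydrochloride, a calcimimetic drug that activates the calcium-sensing receptor. Kidney samples of mice fed cinacalcet, 4 in all, were set against 4 kidney samples of mice on standard chow. The labels word the dose as 1 mg per g body weight and do not state its basis further. The labels give every mouse as male and 12 weeks old. Each RNA was hybridised to 1 one-colour array, and all 8 arrays lay on 1 slide. The 75th percentile of spot intensity ranged from 202.9 to 257.1 between arrays, and 51.8% to 58.0% of spots were well above background. The number of arrays, 4 per group, limits the precision. The labels number the samples without stating that each came from its own animal, so p-values measure the spread between these samples. Levels below are log2 intensities relative to each array's 75th percentile, with SD and n = 4 per group, and fold changes are cinacalcet over control from limma.

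The arrays labelled control 4, cinacalcet 2 and cinacalcet 3 stood apart from the other 5. On these 3 arrays none of the 4 measured Y-linked genes (Ddx3y, Eif2s3y, Uty and Kdm5d) was well above background, and Xist, the X-inactivation transcript of female cells, was at 0.95, 0.46 and 0.73. On the other 5 arrays 3 or 4 of the Y-linked genes were above background. Xist was at -4.22 on cinacalcet 1, which had all 4 Y-linked genes above background, and at -6.99 to -6.38 on the rest. It was well above background on 1 control array and 3 cinacalcet arrays. The first principal component, with 56.0% of the variance, placed control 4, cinacalcet 2 and cinacalcet 3 at 25.3, 43.5 and 43.1, and the other arrays between -37.3 and -2.41. Control 4 correlated with cinacalcet 2 and 3 at r = 0.986 to 0.989 across genes, which are not independent replicates, and with controls 1 to 3 at 0.978 to 0.980. The control group thus held 1 array without Y-linked signal and the cinacalcet group 2. Values with this split as a block, and on the 5 arrays with Y-linked signal, were added after seeing the data and are given below for part of the results and as counts.

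**Figure D1:**
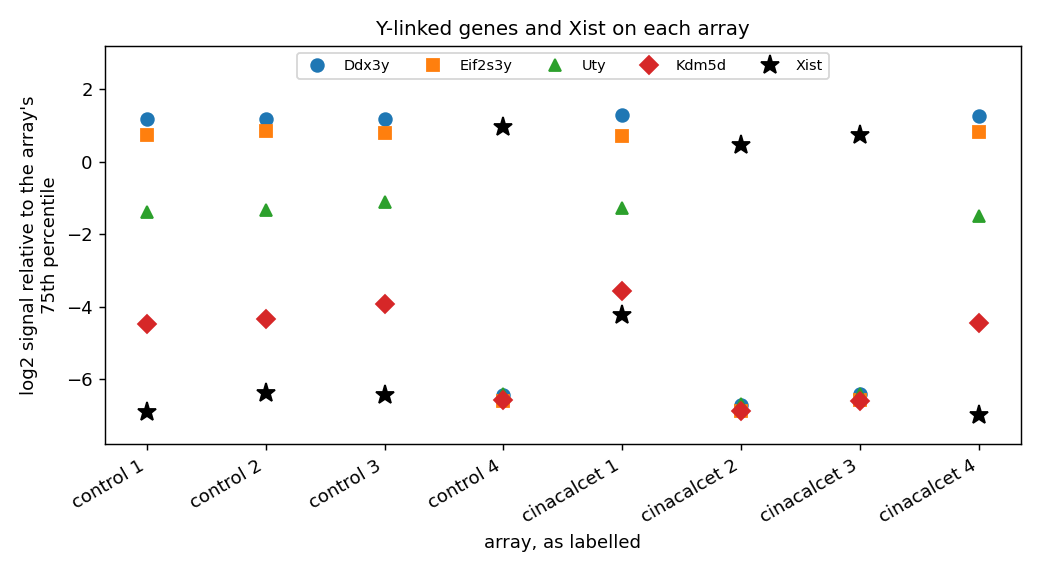
Log2 signal relative to the array's 75th percentile (y axis) of 4 Y-linked genes and Xist on each of the 8 arrays (x axis, as labelled), 1 symbol per gene. Control 4, cinacalcet 2 and cinacalcet 3 have Xist at 0.46 to 0.95 and the Y-linked genes near the bottom of the scale.

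The first question was whether cinacalcet changed genes of renal calcium handling. Cldn14, a claudin of the thick ascending limb that restricts paracellular calcium passage, rose from -4.16 ± 0.84 to -0.33 ± 0.84 (limma adjusted p = 0.0104), a log2 fold change of 3.83 (SE 0.51), or 1.75 with normexp background correction. Its signal was higher on all 4 cinacalcet arrays than on all 4 control arrays, of which 2 were well above background. The array labelled control 4, at -2.92, was the highest control and lay below the lowest cinacalcet array at -1.07. The log2 fold change was 3.44 with Y-linked signal as a block (adjusted p = 2.01e-05), 3.51 on the 5 arrays with Y-linked signal and 3.32 on the other 3. S100g, which encodes the calcium-binding protein calbindin-D9k, fell 1.96-fold from 7.17 ± 0.42 to 6.19 ± 0.31 (adjusted p = 0.0436). Slc34a3, a renal sodium-phosphate cotransporter, fell 1.56-fold (adjusted p = 0.0287).

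Of the other genes of calcium and phosphate handling chosen beforehand, none passed the threshold on the 8 arrays. Casr, the drug's target receptor, was at 1.38 ± 0.22 in controls and 1.90 ± 0.30 with cinacalcet (adjusted p = 0.0941). Cyp27b1, which activates vitamin D, was at -1.40 ± 0.56 and -2.36 ± 0.44 (adjusted p = 0.0931). Calb1, encoding calbindin-D28k, was at -1.03 ± 0.64 and -1.89 ± 0.42 (adjusted p = 0.146). With Y-linked signal as a block these 3 genes passed, with adjusted p of 0.0304, 0.0489 and 0.00637. Cyp24a1, which breaks vitamin D down, had a log2 fold change of 0.68 (adjusted p = 0.207), and the parathyroid hormone receptor gene Pth1r had -0.33 (adjusted p = 0.182, and 0.0459 with the block). Log2 fold changes were -0.09 for Cldn16, -0.11 for Cldn19, -0.13 for Trpv5 and -0.10 for Slc34a1 (adjusted p of 0.608 to 0.791). With the block Cldn16 passed as lower, at -0.24 (adjusted p = 0.0437). Without control 4, the values for Cldn16, Cldn19 and Trpv5 were 0.04, 0.01 and 0.05, and Casr and Cyp27b1 passed (adjusted p of 0.0378 for each). With array weights Casr, Cyp27b1, Pth1r and Cyp24a1 passed (adjusted p of 0.00990 to 0.0454), and on the 5 arrays with Y-linked signal Calb1 did (adjusted p = 0.0397).

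In limits, the Cldn14 call held with each array left out (limma adjusted p of 0.00617 to 0.0378). It was lost with replicate number as a block (limma adjusted p = 0.0849), with slide column as a block (limma adjusted p = 0.0731) and within each slide row of 2 against 2 arrays. The column block, here and below, compares the groups only as control 3 with cinacalcet 2 and control 1 with cinacalcet 3. In each pair only the cinacalcet array lacked Y-linked signal, so this fit cannot separate the drug from that split. The S100g and Slc34a3 calls were lost with most single arrays left out, with adjusted p up to 0.101 and 0.0797.

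Across the kidney transcriptome, 1139 of 14209 genes changed at an adjusted p under 0.05 in limma, 479 higher and 660 lower with cinacalcet. Of these, 213 changed at least 2-fold, 83 higher and 130 lower, and the median absolute log2 fold change was 0.59. The groups did not overlap in 2531 genes, 17.8% of those tested, where chance gives 2.86%. With Y-linked signal as a block 2417 genes passed, and they included all 1139 in the same direction. On the 5 arrays with Y-linked signal 1116 genes passed, 559 of them among the 1139, and all 1139 kept their sign. The count was 320, 218 or 245 without control 1, 2 or 3, and 3356 without control 4. It was 292, 278 or 533 without cinacalcet 2, 3 or 4. Replicate number as a block left 0 genes, with 2869 at an unadjusted p under 0.05 in limma. Slide column as a block left 34 genes, and within slide rows 1 and 2 limma called 1 and 0 genes, with 3860 and 1068 genes at an unadjusted p under 0.05. Without the filter on background 367 genes passed, and with array weights 5438 did.

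The largest rises after Cldn14 were spread over genes of differing function. Skor1, a transcriptional corepressor gene, was not well above background on any control array and was at least 1.64-fold higher with cinacalcet (adjusted p = 0.00789). Such bounds set the bright group's mean against the higher of each dim array's detection floor and its own signal. Zbtb16, a zinc-finger gene induced by glucocorticoids, rose 4.45-fold. Hpd, an enzyme of tyrosine breakdown, rose 4.50-fold, and Hif3a, an inhibitory member of the hypoxia-inducible factor family, rose 4.00-fold. Gpr85, an orphan receptor gene, rose 5.55-fold, Chrdl2, encoding a BMP-binding protein, rose 4.55-fold, and Fgfbp1, an FGF carrier gene, had a log2 fold change of 1.80. S100a9 and Chil3, genes of myeloid cells, rose 3.50-fold and 3.94-fold. Retnlg, above background on 1 of 4 control arrays, had a log2 fold change of 2.60. Gprc5d had a log2 fold change of 1.85 on its brighter probe and 0.83 on its other. With normexp background correction and the 75th percentile the log2 fold changes were smaller, at 0.49 for Retnlg, 0.24 for Skor1, 0.33 for Gprc5d and 0.54 for Fgfbp1, all undetected on some control arrays, and Skor1 and Gprc5d did not pass (adjusted p of 0.109 and 0.0513). With normexp and quantile normalization both did (adjusted p of 0.0159 and 0.00684).

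The largest fall was in Ucp1. Ucp1, the uncoupling protein of brown fat, fell from 0.90 ± 1.90 to -4.83 ± 0.81 (adjusted p = 0.0140), a log2 fold change of -5.73 (SE 0.89), and was above background on 2 of 4 cinacalcet arrays. Ccl12, a chemokine gene for monocytes, was not well above background on any cinacalcet array and was at least 4.79-fold lower (adjusted p = 0.00969). Cd207, the langerin gene of dendritic cells, was at least 2.25-fold lower. Ccr2, a monocyte chemokine receptor gene, and Nod2, a sensor of bacterial peptidoglycan, had log2 fold changes of -2.15 and -2.14. Atp1a4, a sodium pump subunit, was above background on 1 of 4 cinacalcet arrays and fell with a log2 fold change of -3.61, and Gulo, the last enzyme of vitamin C synthesis, fell 4.37-fold. The globin genes Hbb-bt, Hbb-b2 and Hbb-bs fell 5.78-fold, 5.11-fold and 4.38-fold. Alas2, the erythroid enzyme of haem synthesis, fell 4.78-fold, and the globin gene Hbq1a was at least 1.99-fold lower. The beta-globin genes are near-identical in sequence, so their probes may not tell them apart. With normexp background correction and the 75th percentile the log2 fold changes were smaller for the genes undetected on some cinacalcet arrays, at -3.02 for Ucp1, -1.02 for Atp1a4, -0.67 for Ccl12, -0.37 for Cd207, -0.63 for Ccr2, -0.76 for Nod2 and -0.43 for Hbq1a, and Atp1a4 did not pass with normexp and quantile normalization (adjusted p = 0.0576).

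**Figure D2:**
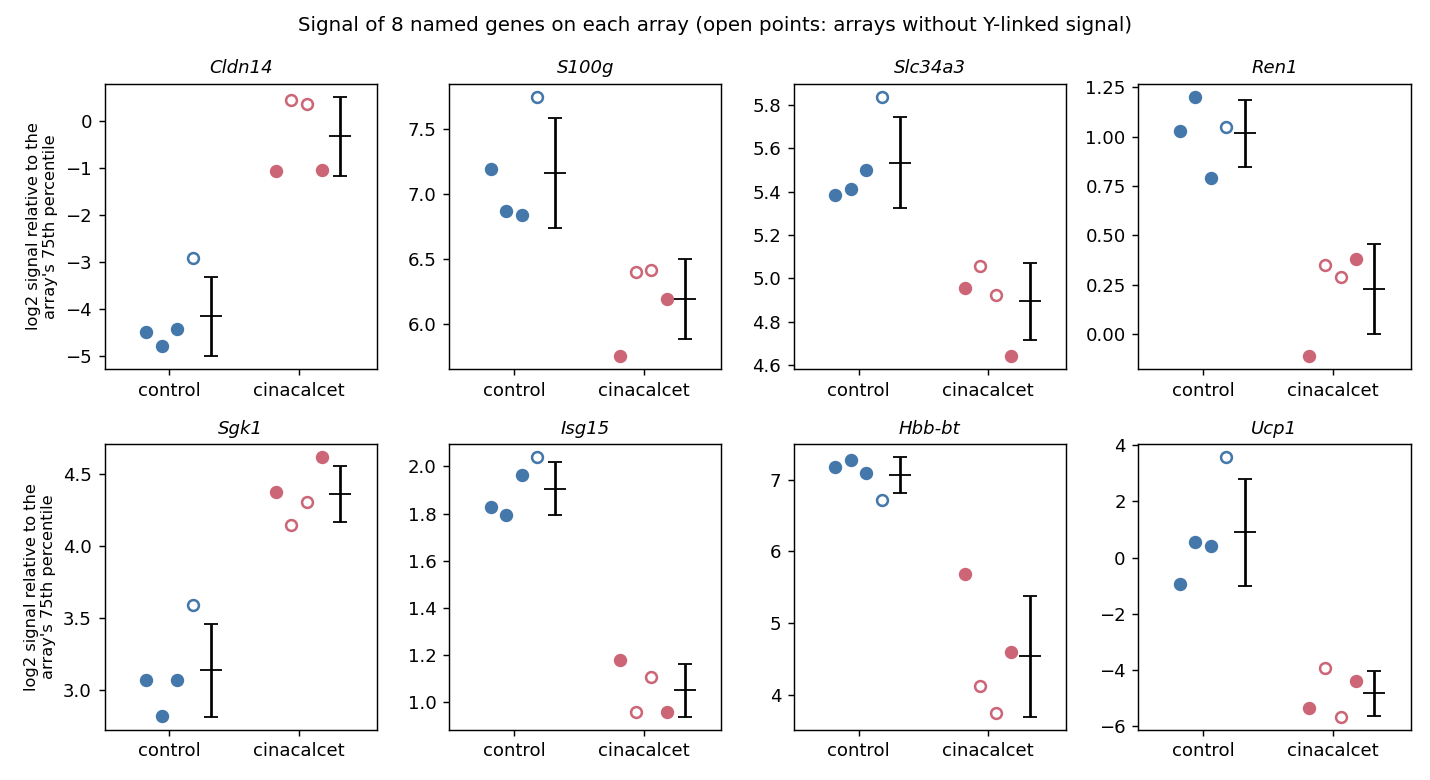
Log2 signal relative to the array's 75th percentile (y axes) of 8 genes on each array by group (x axes). Points are arrays, open where no Y-linked gene was above background, and black bars are the mean and SD of 4 arrays. In each panel all 4 cinacalcet arrays lie on 1 side of all 4 control arrays, as for Cldn14 with -0.33 ± 0.84 against -4.16 ± 0.84.

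Of the 101 genes chosen by rule, 78 passed the threshold and 23 of these also passed with each of the 8 arrays left out. These 23 were Acot1, Ccl12, Ccr2, Cd207, Cdkn1a, Cldn14, Cxcl10, Fgfbp1, Gpr85, Gprc5d, Gulo, Hbb-bt, Ifit1, Isg15, Itgax, Lipa, Per1, Rsad2, S100a9, Sgk1, Skor1, Tnnc2 and Ucp1. The other 55 lost the call without at least 1 array, and none of the 78 changed sign in any such fit. Where groups do not overlap on the 8 arrays, as for 1121 of all 1139 genes called, the sign cannot change with fewer arrays. With Y-linked signal as a block all 78 passed (adjusted p up to 0.0375). On the 5 arrays with Y-linked signal none changed sign and 25 did not pass (adjusted p up to 0.120), namely Acot2, Atp5pb, Atp6v0a4, Ccr2, Cd44, Chordc1, Chrdl2, Cnnm2, Cox6b1, Dnajc3, Gatm, Gstm1, Gstm3, Gulo, Hba-a1, Hexa, Hif3a, Hsp90b1, Nqo1, Pdgfra, Ren1, Scnn1a, Sult1a1, Usp2 and Zbtb16.

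Gene lists fixed beforehand were tested with camera, and 14 of 34 passed at a preset inter-gene correlation of 0.01, 5 higher and 9 lower. None passed with an estimated correlation, where the lowest adjusted p was 0.265, for the glucocorticoid list, the adipose list had 0.675 and the other 12 had 0.673. With fry, which tests whether the genes of a list move one way on balance, 5 lists passed: the interferon, immune cell, glucocorticoid, oxidative phosphorylation and renin-angiotensin lists. Of the 14 lists, 12 also passed with Y-linked signal as a block. The lists of adrenal markers (adjusted p = 0.0771) and lysosome genes (0.0513) did not.

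**Figure D3:**
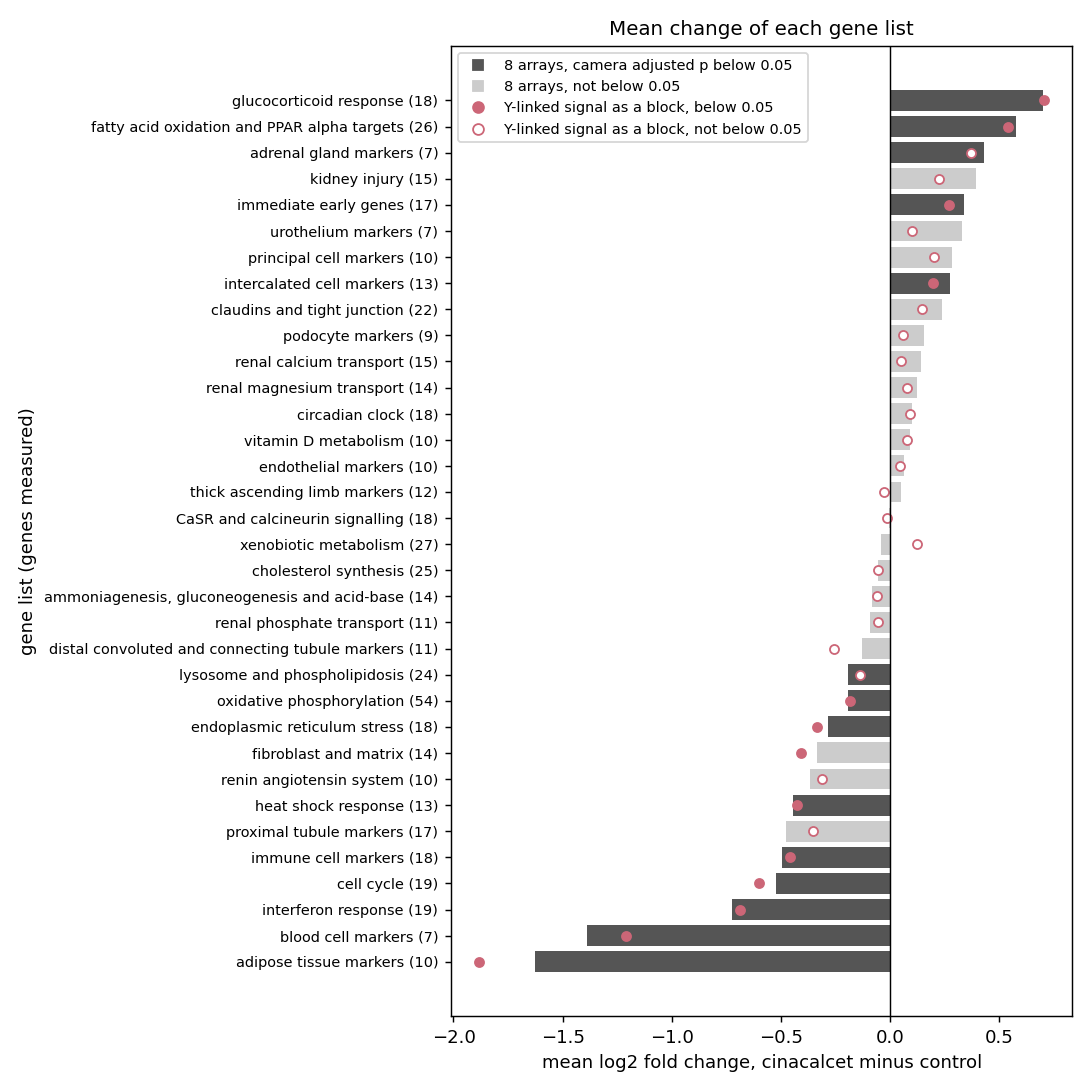
Mean log2 fold change, cinacalcet minus control (x axis), of each of 34 gene lists with the number of genes measured (y axis). Bars are the fit to 8 arrays, dark where camera gave an adjusted p below 0.05, and points are the fit with Y-linked signal as a block, filled where it did. The interferon list lies at -0.72 and the glucocorticoid list at 0.70.

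Interferon-stimulated genes fell as a list. Of 19 measured members 13 fell, 1 rose and 5 did not pass (adjusted over the list alone, 15 fell and 1 rose). The list's camera adjusted p was 1.47e-08, and the adjusted p = 0.673 with an estimated correlation. Isg15, a ubiquitin-like antiviral protein gene, fell 1.81-fold from 1.91 ± 0.11 to 1.05 ± 0.11 (adjusted p = 0.00789). The chemokine gene Cxcl10 fell 3.43-fold, Rsad2, the antiviral gene viperin, 1.69-fold and Ifit1 1.53-fold. Ifit2 was the member that rose, with a log2 fold change of 0.41, and is named after its value was seen.

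Immune cell markers fell as a list while its neutrophil genes rose. Of 18 measured markers 8 fell, 2 rose and 8 did not pass (adjusted over the list alone, 13 fell and 2 rose; camera adjusted p = 0.000423, and adjusted p = 0.673 with an estimated correlation). Adgre1, a macrophage surface antigen gene, fell 3.13-fold, Itgax, encoding CD11c of dendritic cells, 2.27-fold and Csf1r, the receptor for macrophage colony-stimulating factor, 1.47-fold. A dimmer probe of Csf1r gave a log2 fold change of -0.05. The genes that rose were the neutrophil genes S100a9 and, named after its value was seen, S100a8, with log2 fold changes of 1.81 and 1.58. On the 5 arrays with Y-linked signal this list gave an adjusted p of 0.0701, and within slide row 1 0.262. The Adgre1 and Csf1r calls were lost with some single arrays left out (adjusted p up to 0.0656 and 0.0679).

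Glucocorticoid-responsive genes rose as a list. Of 18 measured genes 7 rose, 1 fell and 10 did not pass (adjusted over the list alone, 8 rose and 1 fell; camera adjusted p = 3.73e-06, and adjusted p = 0.265 with an estimated correlation). Sgk1, a kinase that raises sodium transport, rose 2.33-fold from 3.14 ± 0.32 to 4.36 ± 0.19 (adjusted p = 0.0113). The clock gene Per1 rose 1.78-fold, the cell cycle inhibitor gene Cdkn1a 2.97-fold and the sulfotransferase gene Sult1a1 1.70-fold. Immediate early genes also rose as a list, with 2 of 17 members past the threshold, Myc (1.47-fold) and Klf4 (1.57-fold), none lower and the same counts adjusted over the list alone (camera adjusted p = 0.000423, and adjusted p = 0.673 with an estimated correlation). The Myc, Klf4 and Sult1a1 calls were lost with some single arrays left out (adjusted p up to 0.0650, 0.112 and 0.0532).

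Genes of mitochondrial oxidative phosphorylation were lower as a list by a small amount. The mean log2 fold change over 54 genes was -0.19, all 54 estimates were negative, and 6 fell singly (15 adjusted over the list alone). The camera adjusted p was 9.84e-09, and the adjusted p = 0.673 with an estimated correlation. Examples are the complex I gene Ndufa1, which fell 1.33-fold from 7.40 ± 0.10 to 6.99 ± 0.02 (adjusted p = 0.0179), Ndufa4 (1.32-fold), the ATP synthase gene Atp5pb (1.24-fold) and the cytochrome oxidase gene Cox6b1 (1.22-fold). These 4 calls were each lost with some single arrays left out (adjusted p up to 0.117).

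Genes of fatty acid oxidation and PPAR alpha targets were higher as a list, with 4 of 26 higher, none lower and 22 not past the threshold (adjusted over the list alone, 6 higher and 2 lower; camera adjusted p = 0.00223, and adjusted p = 0.673 with an estimated correlation). The list did not pass with slide column as a block (adjusted p = 0.235). The acyl-CoA thioesterase gene Acot1 rose 2.46-fold from 4.46 ± 0.33 to 5.76 ± 0.23 (adjusted p = 0.0113). The related gene Acot2 rose 1.47-fold, and the fatty acid omega-hydroxylase genes Cyp4a10 and Cyp4a31 rose 3.16-fold and 3.13-fold. The Cyp4a genes are close paralogs whose probes may share signal, and the Acot2, Cyp4a10 and Cyp4a31 calls were lost with most single arrays left out (adjusted p up to 0.132).

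Genes of protein folding and lysosomes were lower as lists. All 13 measured heat shock genes had negative estimates, 1 of which passed (9 adjusted over the list alone), namely the HSP90 cochaperone gene Chordc1, which fell 1.65-fold (adjusted p = 0.0428). Of 18 endoplasmic reticulum stress genes 2 fell, the chaperone genes Hsp90b1 (1.36-fold) and Dnajc3 (1.24-fold), and none rose (5 fell adjusted over the list alone). Of 24 lysosome and phospholipidosis genes 2 fell, the acid lipase gene Lipa (1.79-fold) and the hexosaminidase gene Hexa (1.33-fold), and none rose (the same 2 adjusted over the list alone). Of 19 cell cycle genes 3 fell, the proliferation marker Mki67 (3.05-fold), the cytokinesis gene Prc1 (2.64-fold) and Cdc20 (1.97-fold), and none rose (11 lower and 1 higher adjusted over the list alone). Camera gave these 4 lists adjusted p of 0.000327, 0.00605, 0.0315 and 0.00522, and for each the adjusted p = 0.673 with an estimated correlation. Of the genes named here, Lipa kept its call with each array left out, and the others lost it without at least 1 array. The lysosome list lost its call without control 1 or cinacalcet 1, 2 or 3 (adjusted p up to 0.0835), and the endoplasmic reticulum list without control 4 or cinacalcet 4 (adjusted p up to 0.0605). With slide column as a block and with array weights the endoplasmic reticulum list (adjusted p of 0.659 and 0.0580) and the cell cycle list (0.0785 and 0.0872) did not pass, and the lysosome list did not with 3 other alternatives besides the Y-linked signal block (adjusted p of 0.0523 to 0.342).

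Markers of tissues other than kidney also differed. Of 7 blood cell markers 4 fell, the globin genes Hba-a1 (3.77-fold), Hbb-b2 and Hbb-bs and the haem gene Alas2, and none rose (5 fell adjusted over the list alone, camera adjusted p = 0.00173, and adjusted p = 0.673 with an estimated correlation). Hba-a1 went from 8.84 ± 0.21 to 6.92 ± 0.76, and these 4 calls were lost with some single arrays left out (adjusted p up to 0.0691). Of 10 adipose markers Ucp1 alone passed, over all genes or adjusted over the list alone, and the list's mean log2 fold change was -1.63 (camera adjusted p = 0.0348, and adjusted p = 0.675 with an estimated correlation). Without control 4, cinacalcet 1 or cinacalcet 3 the adipose list did not pass (adjusted p up to 0.277), nor did it on the 5 arrays with Y-linked signal (0.0594) or with 6 other alternatives (0.0523 to 0.450), slide column as a block among them. None of 7 adrenal markers passed over all genes (1 adjusted over the list alone), and the list was higher (camera adjusted p = 0.0315, and adjusted p = 0.673 with an estimated correlation). The steroidogenic gene Hsd3b1, above background on 2 of 4 control arrays, had a log2 fold change of 1.67 (adjusted p = 0.0592) and Nr5a1 had 0.25 (adjusted p = 0.143). The adrenal list did not pass without control 1 or cinacalcet 4 (adjusted p up to 0.0973), or with 5 alternatives besides the Y-linked signal block (0.0741 to 0.189). With the block Hsd3b1 passed (adjusted p = 0.0459), as it did with normexp background correction at a smaller log2 fold change of 0.41 (0.0498, or 0.45 and 0.0225 with quantile normalization) and in some other alternatives, and Nr5a1 passed with array weights and without control 4. Of skeletal muscle markers 4 were measured, too few for the list test, and the troponin gene Tnnc2 had a log2 fold change of 0.87 from near background. With normexp and the 75th percentile or quantile normalization it was smaller, at 0.14 and 0.19, and did not pass (limma adjusted p of 0.221 and 0.0660). None of 7 urothelium markers passed (list adjusted p = 0.187), with log2 fold changes of 0.67 for Upk1b and 0.25 for Krt7, which passed with array weights. The urothelium list passed with array weights (adjusted p = 0.0166), with slide column as a block (0.0441), within slide row 1 (0.000113) and without cinacalcet 4 (0.0374).

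Among nephron segments, intercalated cell markers were higher as a list. Of 13 markers 2 rose, the proton pump subunit gene Atp6v0a4 (1.42-fold) and the bicarbonate transporter gene Slc4a9 (1.53-fold), and none fell (4 rose adjusted over the list alone, camera adjusted p = 0.00267, and adjusted p = 0.673 with an estimated correlation). Of 10 principal cell markers 1 rose, the epithelial sodium channel gene Scnn1a (1.59-fold, list adjusted p = 0.0504). Of 17 proximal tubule markers 1 fell, the creatine synthesis gene Gatm (2.27-fold, list adjusted p = 0.685). None of 12 thick ascending limb markers passed (list adjusted p = 0.674), with a log2 fold change of -0.36 for Cldn10. Of 11 distal convoluted and connecting tubule markers S100g alone fell (list adjusted p = 0.969). None of 9 podocyte markers (Wt1 at 0.47) and none of 10 endothelial markers (Flt1 at 0.30, Pecam1 at 0.23) passed, where the podocyte list's adjusted p was 0.124 and the endothelial list's unadjusted camera p was 0.169. Adjusted over the list alone, 2 thick ascending limb markers passed, and the counts of the other 5 lists, intercalated cells aside, were those over all genes. The principal cell list passed in 9 alternatives (adjusted p of 0.00312 to 0.0480) and without control 1, control 4, cinacalcet 1 or cinacalcet 4. The podocyte list passed with array weights (0.0101), with slide column as a block (0.00136) and without control 4 or cinacalcet 1, and the thick ascending limb and distal tubule lists passed with slide column as a block (0.0484 each). With Y-linked signal as a block, and in some other alternatives, Cldn10 and Flt1 passed (adjusted p of 0.0432 and 0.0381 with the block), and with array weights Wt1 did. The calls of Atp6v0a4, Slc4a9, Scnn1a and Gatm were lost with some single arrays left out (adjusted p up to 0.131).

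The lists of mineral transport did not pass as lists on the 8 arrays. The claudin list passed with array weights (adjusted p = 0.0210), with slide column as a block (0.00487), within slide row 1 (0.0181) and without cinacalcet 4 (0.0346). Of 22 claudin and tight junction genes and of 15 calcium transport genes Cldn14 was the member that rose (list adjusted p of 0.204 and 0.895), and S100g fell among the latter. Of 14 magnesium transport genes 11 had positive estimates and 2 fell, Pcbd1, a cofactor of a transcription factor for renal magnesium genes (1.34-fold), and Cnnm2, a basolateral magnesium gene (1.29-fold). Of 11 phosphate transport genes Slc34a3 fell, and 2 fell adjusted over the list alone. Of 18 genes of calcium-sensing receptor and calcineurin signalling the phospholipase gene Plcb1 fell 1.35-fold, while its other probe gave a log2 fold change of 0.03. The Pcbd1, Cnnm2 and Plcb1 calls were lost with some single arrays left out (adjusted p up to 0.0812). None of 10 vitamin D genes passed. These last 4 lists had adjusted p of 0.187, 0.685, 0.839 and 0.539, and apart from phosphate transport the counts adjusted over the list alone equalled those over all genes. The mean, the median and the test disagreed in sign for the lists of calcium transport, distal tubule, xenobiotic, cholesterol and clock genes.

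The remaining lists did not pass with camera on the 8 arrays. Renin, Ren1, fell 1.73-fold from 1.02 ± 0.17 to 0.23 ± 0.23 (adjusted p = 0.0183), the converting enzyme gene Ace fell 1.45-fold and angiotensinogen, Agt, rose 1.45-fold (1 of 10 higher and 2 lower, 3 and 4 adjusted over the list alone, list adjusted p = 0.685). Of 14 fibroblast and matrix genes 4 fell, among them the collagen genes Col3a1 (2.69-fold), Col1a1 (2.42-fold) and Col1a2 (1.59-fold), and Pdgfra rose 1.52-fold (7 lower and 2 higher adjusted over the list alone, list adjusted p = 0.0869, and 0.0250 with Y-linked signal as a block). Of 15 kidney injury genes Cdkn1a rose and Cd44 fell 2.10-fold (2 higher and 1 lower adjusted over the list alone, list adjusted p = 0.0954). Of 27 xenobiotic genes 4 rose, Nqo1 (1.78-fold), Cyp1b1 (1.61-fold), Gstm3 (1.45-fold) and Gstm1 (1.43-fold), and none fell (6 higher and 3 lower adjusted over the list alone, list adjusted p = 0.186). Of 18 clock genes Per1 and Usp2 (1.56-fold) rose and Dbp fell 1.48-fold (4 higher and 1 lower adjusted over the list alone, list adjusted p = 0.536). None of 25 cholesterol synthesis genes passed, with log2 fold changes of 0.77 for Fdft1 and -0.59 for Cyp51 (list adjusted p = 0.969). None of 14 genes of ammonia, glucose and acid-base metabolism passed, with -0.65 for G6pc and -0.47 for Fbp1 (list adjusted p = 0.617). The fibroblast list also passed without the background filter (adjusted p = 0.0445) and without control 1, control 2 or cinacalcet 2, and the injury list in 4 alternatives (0.00767 to 0.0492) and without control 4 or cinacalcet 4. The xenobiotic list passed without the background filter (0.0474) and on the 5 arrays with Y-linked signal (0.0464). With Y-linked signal as a block, and in some other alternatives, Fdft1, Cyp51 and Fbp1 passed (adjusted p of 0.0231, 0.0282 and 0.0131 with the block), and with array weights and without control 4 G6pc did. All single-gene calls in this paragraph except those of Per1 and Cdkn1a were lost with some single arrays left out (adjusted p up to 0.125).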

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

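Of the tests reported here, those of weak hybridization, of female tissue, of erythroid transcripts and of Ucp1 were chosen only after the result was seen, and the second test of control 4 was added because of the outcome of the first. Dixon's test on the named genes and on 2 array measures gave 6 samples far from the other 3 of their group, in 206 group tests, where chance gives about 1 in 20.

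Among controls, Cldn19 on control 4 was the highest at 1.34 (gap over range 0.882), and so was S100a9 on control 4 at 0.37 (0.856). Among cinacalcet arrays, Cyp1b1 was lowest on cinacalcet 3 at 1.07 (0.845). Cyp4a10 was lowest on cinacalcet 1 at 7.28 (0.887). Hif3a was highest on cinacalcet 4 at 1.41 (0.930). Pcbd1 was lowest on cinacalcet 4 at 6.58 (0.981).

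The arrays labelled control 4, cinacalcet 2 and cinacalcet 3 lacked Y-linked signal although the labels give male mice. Weak hybridization is argued against, since the lowest Xist on these arrays lay 4.68 log2 units above the highest on the other 5. Tissue of female mice may account for the pattern but the test left it open: 3 of the 4 Y-linked genes were above background on all of the other 5 arrays and on none of the 3, since control 2 had 3 of them above background, and a looser count tried after that outcome found all 4 lower on each of the 3 arrays than on each of the other 5. A wrong treatment label on control 4 stays open: on a scale from control (0) to cinacalcet (1), over 200 genes chosen on the arrays with Y-linked signal, control 4 lay at 0.731, where a wrong label predicted 0.5 or more, but cinacalcet 2 and 3 lay at 1.30 and 1.25 against 0.552 and 0.939 for cinacalcet 1 and 4, so position also varies with Y-linked signal. The second test, over 200 genes chosen on all arrays but control 4, put it at 0.496, below the lowest held-out cinacalcet array at 0.578 by less than their SD of 0.241, and above the held-out controls (0.0557 to 0.107). That lowest array was cinacalcet 1, which has Y-linked signal. Cinacalcet 2 and 3, which lack it as control 4 does, lay at 1.11 and 1.05, well above control 4. The held-out controls all have Y-linked signal, so this test does not separate treatment from that split either.

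Erythroid transcripts differed by -2.16 log2 units between cinacalcet and control over Hba-a1, Hbb-b2, Hbb-bs and Alas2. The globin genes Hbb-bt and Hbq1a were measured too but lie outside the blood cell list. Those first 4 genes are the measured erythroid members of the list and also its members that passed, so no test of their mean is given. Less blood left in the cinacalcet kidneys would lower platelet transcripts (Pf4, Ppbp and Itga2b) as much. The erythroid minus platelet difference was -1.81 between groups, or -1.79 with normexp background correction against group SDs of 0.19 and 0.60. The platelet mean was itself -1.52 ± 0.34 in controls and -1.88 ± 0.32 with cinacalcet, dimmer than the erythroid mean at 5.53 and 3.37. On the 5 arrays with Y-linked signal the platelet means of the groups did not overlap. The difference reuses the same 4 genes, so it describes their fall relative to platelet genes and is not a separate test. The neutrophil genes S100a8 and S100a9 were higher by 1.69. With Y-linked signal as a block the log2 fold changes of the 4 genes were -1.72 to -2.14 (SE up to 0.28, limma adjusted p up to 0.00683), so the fall remained in that fit. All 1139 genes called on the 8 arrays also passed with this block. For genes already called on the same arrays it therefore cannot decide whether unequal numbers of arrays without Y-linked signal were the whole cause. The tests of these genes and of Ucp1 replaced first ones that rested on no overlap between groups, since the genes had been picked or had passed with groups that did not overlap on all 8 arrays. A change in the make-up of the blood under the drug remains open as a hypothesis and was not tested further.

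Ucp1 differed by -5.73 log2 units between cinacalcet and control. Less adipose tissue attached to the cinacalcet kidneys would lower general adipose transcripts (Adipoq, Plin1, Cidec, Cfd, Fabp4, Retn and Car3) as much, and it stays open: the Ucp1 minus general adipose difference was -4.56 between groups, but -2.09 with normexp background correction, within the sum of the group SDs of 1.17 and 1.07, and Ucp1 was above background on 2 of 4 cinacalcet arrays. The general adipose mean was 2.17 ± 1.25 in controls and 1.00 ± 1.49 with cinacalcet. Ucp1 gave -6.12 with Y-linked signal as a block (SE 0.78, limma adjusted p = 0.00562), so its fall remained in that fit. As for the erythroid genes, this block cannot decide whether unequal numbers of arrays without Y-linked signal were the whole cause. A fall of Ucp1 within attached fat may remain as a biological hypothesis, and a change in the kind of fat attached was not tested.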

How the results depend on the processing

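The Y-linked signal block and the fit to arrays with Y-linked signal only were chosen after seeing the data, and the other alternatives before. A list's direction is the sign of its mean log2 fold change, a rule set after the alternatives were seen in place of the direction of the camera test. Where no cause is given, the cause was not tested. The effect with slide column as a block rests on pairs in which only the cinacalcet array lacked Y-linked signal. That fit cannot separate the drug from this split. Changed genes numbered 367 (156 higher, 211 lower) without a filter on background, 5438 (2021, 3417) with array weights, 34 (12, 22) with slide column as a block, 1 (0, 1) within slide row 1 and 0 (0, 0) within slide row 2, where few arrays remained. There were 2417 (944, 1473) with the Y-linked signal block and 1795 over all kept probes, 1010 of them higher. With an array left out the count ran from 218 (without control 2) to 3356 (without control 4), higher genes from 90 to 1114 and lower genes from 128 to 2242. Cldn14's log2 fold change was 4.86 (adjusted p = 0.0731) with slide column as a block, 4.25 (0.129) within slide row 1 and 3.40 (0.399) within slide row 2, not past the threshold, and 1.75 to 4.86 over all alternatives, 3.57 to 4.24 with an array left out. Above background on all 8 arrays, Cldn14 was not tested, as 2 of 4 controls were above it. Lists past the threshold numbered 0 with an estimated correlation, 5 with fry, 11 to 17 in the other alternatives and 12 to 16 with an array left out.

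With replicate number as a block limma called 0 genes (0 higher, 0 lower; 2869 at an unadjusted p under 0.05), and Cldn14's log2 fold change was 3.83 (adjusted p = 0.0849). Whether the numbers pair the samples stays open. Deviations of same-numbered arrays correlated at 0.337, -0.544, -0.360 and -0.565, and only control 1 correlated best with its own number. Numbers 2, 3 and 4 each match an array with Y-linked signal to an array without it, so these correlations cannot decide on pairing.

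Values not past the threshold turned sign as follows. With array weights Cldn16 was 0.15, Cldn19 0.0312 and Trpv5 0.13, the receptor signalling list's mean 0.0126 and the distal tubule list's 0.0977. With slide column as a block Cldn16 was 0.32, Cldn19 0.12 and Trpv5 0.20, receptor signalling 0.0402, cholesterol 0.000179 and distal tubule 0.23 (adjusted p = 0.0484). Within slide row 1 Cldn16 was 0.11, Trpv5 0.22, receptor signalling 0.000560 and distal tubule 0.0653. Within slide row 2 Cyp24a1 was -0.0782, Slc34a1 0.0236, ammonia and glucose metabolism 0.00362, cholesterol 0.0228, thick ascending limb -0.0452, urothelium -0.18 and xenobiotic 0.17. The receptor signalling mean was 0.0162 with quantile normalization, 0.0109 with normexp and quantile, and 0.00464 over all probes of a gene. Xenobiotic was 0.00783 without the filter (adjusted p = 0.0474), 0.12 with the Y-linked signal block and 0.17 with Y-linked signal only (adjusted p = 0.0464). Thick ascending limb was -0.0267 with the Y-linked signal block, and calcium transport -0.12 above background on all 8 arrays. With an array left out, values ran from -0.207 to 0.0402 for Cldn16, -0.169 to 0.0144 for Cldn19, -0.247 to 0.0452 for Trpv5, -0.0162 to 0.00864 for receptor signalling, -0.204 to 0.0294 for distal tubule, -0.00197 to 0.145 for thick ascending limb and -0.204 to 0.0898 for xenobiotic. Dim probes near background limit the level of genes such as Skor1, whose control values are bounds.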

Other observations

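The values of Cirbp, Slc7a13 and Slco1a1 were picked out only after they were seen, and the test of Rbm3 was written before its value was seen. Both cold-induced RNA-binding protein genes were higher with cinacalcet, and neither is among the genes named by rule. Cirbp was at 2.70 ± 0.33 in controls and 4.32 ± 0.25 with cinacalcet (limma adjusted p = 0.00801, n = 4 per group), higher on 4 of 4 arrays, and with Y-linked signal as a block its log2 fold change was 1.61. Rbm3 was at 3.60 ± 0.12 and 4.52 ± 0.24, higher on 4 of 4 arrays, with a log2 fold change of 0.92 and an adjusted p of 0.0109 in limma, but of its 3 kept probes 1 gave a log2 fold change of -1.04. All 13 heat shock genes had negative estimates in the same arrays. These values are consistent with a lower body temperature of the cinacalcet-fed mice, a hypothesis for which Rbm3 was the test, and the opposed probe and the absence of temperature data leave it open.

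The levels of Slc7a13 and Slco1a1 are given for each array and were picked out after their values were seen. Slc7a13 is a member of the proximal tubule list, whose mean log2 fold change was -0.48 and median -0.10. Its own log2 fold change was -3.88 (limma adjusted p = 0.429). Slc7a13, an amino acid transporter gene of the male proximal tubule, was at -3.29, -5.63 and -5.61 on control 4, cinacalcet 2 and cinacalcet 3, and between 3.74 and 5.37 on the other 5 arrays. Slco1a1, an organic anion transporter gene, was at -3.16, -4.41 and -4.30 on the same 3 arrays. On the arrays with Y-linked signal it was at 3.19, 3.46 and 3.37 in controls and at 1.66 and 1.23 with cinacalcet. No gene passed an adjusted p of 0.05 in limma for a difference in the cinacalcet effect between arrays with and without Y-linked signal, and 1814 did at an unadjusted p under 0.05, in a design with 1 control array lacking that signal.

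Among 11129 unnamed probes 655 changed, 506 higher and 149 lower, in a fit over all 29730 kept probes, so the share of rises was larger than among named genes. Their identity was not analysed here.

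Chance is argued against, but not excluded, for the gene count. Among the 35 splits of the 8 arrays into 4 and 4, only the real one gave 1139 genes or more. This is 1 of 35, the least that any result can reach with so few arrays. The highest other, controls 1 to 3 with cinacalcet 1 against the rest, gave 570. It put all 3 arrays without Y-linked signal on the same side. For Cldn14 the absolute t of 7.44 was likewise reached in 1 of 35 splits, the real one, against 2.88 at most in the others. Chance is not argued against for the number of gene lists: 5 of 35 splits gave 14 lists or more, up to 19. One of these was the split by slide row, with 15 lists, and with slide row as a block 15 lists passed for cinacalcet.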
